A study of Mus musculus with 2 samples.

How the data were processed

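RNA was measured in 2 cultures of 3T3-L1 cells, a mouse fibroblast line that can be turned into adipocytes in culture. One culture received a control siRNA and the other an siRNA against Pink1, and each gave 1 library. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a QuantSeq kit, which sequences tags from the 3′ ends of transcripts. The labels call the cells adipocytes. The read length, the time after transfection and the days of differentiation were not given in the sources used here.

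Per the submitters' processing notes, bcl2fastq 2.20.0.422, Bowtie2 and bedtools were used with the mm10 mouse genome build. Which gene annotation was used, how multiply mapped reads were placed and whether strand was used in counting was not given in the sources used here. The deposited values are read counts per gene symbol, not normalized, with 1 table per library. The unit was read from the values, which are whole numbers with unequal library totals. No molecular identifiers are mentioned in the labels, so a count is a number of reads, and reads copied from 1 molecule cannot be separated.

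Each table held 23282 rows with the same symbols in the same order. Of these, 79 rows shared 35 symbols, and they were counted but not named. No row lacked a symbol. Symbols in the gene lists that were absent from the tables were looked up as RefSeq synonyms, which matched 9 of them. Of 23238 distinct symbols, 22024 were in the RefSeq gene table of GRCm38.p6, the assembly behind mm10, which gave the gene coordinates (1-based). The precursor ribosomal RNA row, Rn45s, held 10.8% of the control counts and 9.83% of the Pink1 siRNA counts and was kept.

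Levels are given as CPM over effective library sizes. Counts were scaled by trimmed mean of M values (TMM) effective library sizes from edgeR 4.0.16 in R 4.3.3. The log2 ratio was that of scaled counts with 0.5 added, Pink1 siRNA over control siRNA. A gene was called measured when its counts summed to at least 40, which held for 11660 rows. The 95% interval of a ratio was the exact conditional binomial (Clopper-Pearson) interval of the 2 counts (SciPy 1.17.1). Such intervals and floors cover counting error only. A count of 0 allows up to 3 counts, or 0.214 CPM in each library.

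With 1 library per group there is no replicate check, and no p-value was computed. Genes were described by a rule of size: a measured gene was called higher or lower when its ratio was at least 2 either way and its counting interval left out 1. Lists of genes were described by the median log2 ratio of their measured members and its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. A list outside the central 95% of random lists is described as standing apart. The percentile treats members as independent, which genes of 1 pathway are not. It describes these 2 libraries, not the 2 conditions.

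Named genes were chosen by a fixed rule. They were the anchor genes fixed in advance, the 10 largest and 10 smallest ratios among genes past the rule with at least 50 counts in the higher library, the 5 highest and 5 lowest ratios among genes averaging at least 100 CPM, and up to 4 measured members of each list with the largest log2 ratio in size. Predicted genes, clones and small RNAs were not named, and some genes that the rule takes are not reported here. Of the 176 named genes, 24 overlap another gene with at least 40 counts, and their counts are uncertain because strand use in counting is unknown. Not every such overlap is marked again where the gene is named. The rule of size, the 40 gene lists, the naming rule and the alternatives were fixed before the data were examined, except for 3 alternatives. Those were 2 intervals widened for the excess spread between the libraries and a removal of the trend on GC content and transcript length.

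The excess spread was measured as the squared difference of the 2 counts over its binomial variance. It averaged 6.30 (bootstrap 95% interval 5.99 to 6.63) over the 2915 measured genes with the lowest mean level. It was larger for abundant genes, reaching 128 in the highest twentieth. The widened interval of a gene divides both counts by the factor of its own twentieth of mean level. It does not separate technical spread from real differences between the cultures. Within a twentieth it is narrower for genes with more counts, as the highest twentieth shows. There, Dlk1 and Col1a1 had widened intervals above 1 although their log2 ratios lay within the interquartile range (-0.08 to 0.21). An interval with the common factor of 6.30, which is too narrow for abundant genes, was the other widened interval. GC content and length came from the longest GENCODE M21 transcript of each symbol, found for 99.3% of measured genes. The other alternatives were total-count, DESeq2 (1.42.0) median-of-ratios and upper-quartile scaling, 5 added before the log, no filter and a summed count of 200, ratios of 1.5 and 4, no counting interval, random lists without matching, and summed values in place of medians.

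The rule and the list percentile were tested on simulated data drawn from the real mean counts and library sizes, with 200 genes altered. With counting error alone, all 67 genes altered by 2.5-fold and all 66 altered by 4-fold passed the rule, none of the 67 altered by 1.5-fold did, and 7 unaltered genes passed. With the spread seen in those 2915 genes, 54 of 67 and 66 of 66 passed at 2.5-fold and 4-fold, with 9 of 67 at 1.5-fold and 489 unaltered genes, or 92 unaltered genes with the interval widened by the common factor. That spread was estimated from the differences between these same libraries, so these numbers are no independent measure of chance. Of 100 unaltered lists of 30 genes, 8 stood apart with counting error alone and 6 under that spread. When shifted by 0.2 on the log2 scale, 100 and 97 of 100 did.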

Results

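The series profiled polyadenylated 3′ ends in 3T3-L1 cells given an siRNA against Pink1 or a control siRNA. Pink1 encodes a mitochondrial kinase that marks damaged mitochondria for removal, and the series title places the comparison in the setting of age-related bone loss. There was 1 library per group. The control library held 13803174 counts over 14682 rows with a count, and the Pink1 siRNA library held 14214768 counts over 14432 rows. Every value below is therefore a single measurement per group, its interval covers counting error only, and no difference has a replicate check.

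Pink1 itself was lower in the Pink1 siRNA library, at 25.1 against 36.5 CPM, a 1.46-fold difference from 351 and 511 counts. The ratio was 0.687 with a 95% counting interval of 0.598 to 0.788. The interval widened for the spread between the libraries among genes of its level was 0.445 to 1.05, which includes 1. The gene lies on chromosome 4 from 138313409 to 138326296 (mm10). Its log2 ratio of -0.54 was short of the rule of size, and 22 of the 582 genes of similar level had a ratio as low or lower. The direction goes with the labels, with a 31.3% lower level.

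As a group, mitophagy genes did not stand apart from random lists. Of the 30 measured members of the mitophagy list, which includes Pink1, none passed the rule of size in either direction. Their median log2 ratio was 0.11, at percentile 94.8 of random lists. The adaptor Optn had a log2 ratio of -0.98 from 127 and 64 counts, just under the rule. The mitochondrial ubiquitin ligase Mul1 had 0.52 and the autophagy regulator Ambra1 had 0.43, and all 3 widened intervals included 1. In the wider autophagy and lysosome list, the median of 39 genes was 0.03 (percentile 52.1), and none passed the rule. Its lysosomal regulators Tfeb and Tfe3 had log2 ratios of 0.86 and 0.41, with widened intervals that included a ratio of 1 for both.

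Across the transcriptome, most measured genes had ratios near 1, but the differences exceeded counting error at every level of expression. Over the 11660 measured genes the log2 levels had a Pearson r of 0.975 and a Spearman rho of 0.984 across genes, which are not independent replicates. The ratio was within 1.5-fold for 87.0% of them. By the rule of size, 190 genes were higher and 279 lower in the Pink1 siRNA library. Most were weakly expressed, since 455 of these 469 had no more than 400 counts in both libraries together. How many of these go beyond the spread between cultures cannot be tested with 1 library per group. With the widened interval, 48 were higher and 81 lower.

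**Figure D1:**
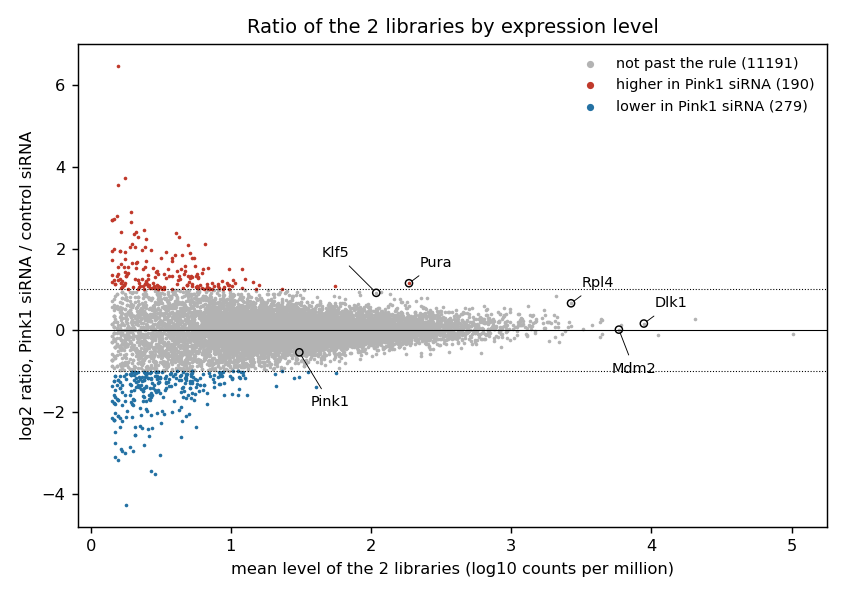
Each point is 1 of the 11660 measured genes, with the mean level of the 2 libraries (log10 CPM) on the x axis and the log2 ratio of Pink1 siRNA over control siRNA on the y axis; dotted lines mark a ratio of 2 either way. Genes past the rule of size (190 higher, 279 lower) lie mostly at low levels, and genes with 0 counts in 1 library take extreme ratios that depend on the added 0.5.

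Among abundant genes, those averaging at least 100 CPM, 1 of 1874 passed the rule. It was Pura, a nucleic acid-binding protein gene on chromosome 18 from 36280560 to 36292535, at 257 against 116 CPM. Its ratio was 2.22 (counting interval 2.10 to 2.36). The next highest were Dnali1, an axonemal dynein light chain gene (1.91-fold), Klf5, an early adipogenic transcription factor (1.89-fold), Xdh, xanthine dehydrogenase (1.86-fold), and Arpc1b, an actin-nucleating Arp2/3 subunit (1.78-fold). Their widened intervals all lay above 1. Dnali1 overlaps Gnl2 by 44 bases, and Gnl2 went from 1932 to 3133 counts, so their reads may not be separable. The lowest abundant genes were Pdia4, an endoplasmic reticulum disulphide isomerase (ratio 0.644), Enpp2, the secreted enzyme autotaxin (0.650), Bzw1 (0.668), Fam104a (0.670) and Acta2, smooth muscle actin (0.673). Widened intervals lay below 1 for Pdia4, Enpp2, Bzw1 and Fam104a and included 1 for Acta2, and Fam104a overlaps Cog1 (275 and 144 counts).

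The largest differences past the rule came from few reads. The 10 highest ratios with at least 50 counts were in Tnn, Ttc39aos1, Disp2, Acsf2, Prkd1, Mef2b, Xylb, Phf11c, Spata2l and Tcn2. They ran from 5.48-fold for Tnn, a matrix glycoprotein gene (10 and 57 counts), to 3.69-fold for Tcn2, the vitamin B12 carrier transcobalamin (30 and 112 counts). Acsf2, an acyl-CoA synthetase, went from 20 to 100 counts. The 10 lowest were D6Ertd527e, Kif24, S100pbp, Camp, Alpk1, Pcdhga11, Parp16, Prtg, Gprasp2 and Ankdd1b. They ran from 10.8-fold lower for D6Ertd527e (70 and 6 counts) to 4.81-fold lower for Ankdd1b (74 and 15 counts). Widened intervals included 1 for Disp2 and Phf11c, and with a common widening factor also for Prkd1, Spata2l, Alpk1, Pcdhga11 and Gprasp2. Pcdhga11 shares its 3′ exons with the rest of its cluster, Phf11c has close paralogs and Ttc39aos1 is an antisense gene, so their counts are uncertain. Ttc39a, which Ttc39aos1 overlaps, had few reads itself (7 and 3 counts). Also uncertain are Gprasp2, which overlaps Bhlhb9 (391 and 386 counts), and Ankdd1b, which overlaps Poc5 (122 and 128). Spata2l overlaps Cdk10 by 2 bases (327 and 390 counts).

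Of the 40 fixed lists, 34 had at least 5 measured members, and 7 of these stood apart from random lists, against 1.7 expected by chance if members were independent. The groups above were the cytosolic ribosomal proteins and fatty acid oxidation. Those below were fatty acid and triglyceride synthesis, interferon response, myofibroblast and TGF-beta response, cell cycle and proliferation, and replication-dependent histones. No member was shared between any pair of the 7.

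**Figure D2:**
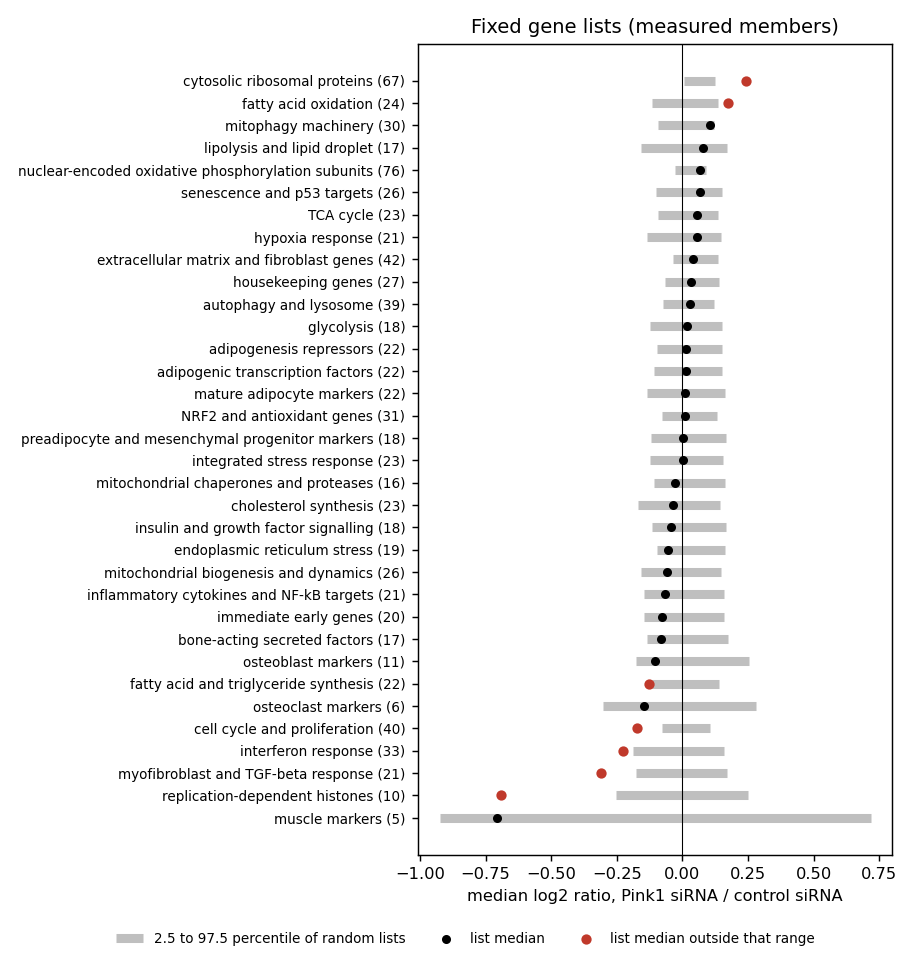
Dots give each list's median log2 ratio of Pink1 siRNA over control siRNA (x axis), with the number of measured members in brackets; grey bars span the central 95% of 10000 random lists matched on level. The 7 red medians lie outside their bar, from -0.69 for replication-dependent histones to 0.24 for cytosolic ribosomal proteins.

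Cytosolic ribosomal protein genes were higher as a group in the Pink1 siRNA library. All 67 were measured, 62 had a ratio above 1, and the median was 1.18-fold (log2 0.24), above all 10000 random lists. Together they took 5.11% of that library's counts against 4.36% of the control counts. The random lists matched on level were themselves shifted upward, with a middle value of log2 0.075 and most between 0.005 and 0.125. Part of the 1.18-fold difference, of the 62 ratios above 1 and of the larger share of counts is therefore common to genes of such levels. Rpl4 had 45807 against 28978 counts (1.58-fold), Rps27 was 1.54-fold, Rpl12 1.48-fold and Rps12 1.45-fold higher. None passed the rule of size, while 12, these 4 among them, had a widened interval above 1 and 0 below. Ribosomal protein genes have many near-identical pseudogenes, so the counts of single members are uncertain.

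Proliferation genes were lower as a group. Of 40 cell cycle genes, all measured, 29 had a ratio below 1, with a median 1.13-fold lower (log2 -0.17) that lay below all 10000 random lists. The replication licensing factor Cdc6 was 1.58-fold lower (274 and 173 counts), cyclin E1 gene Ccne1 1.55-fold, the spindle checkpoint kinase gene Bub1b 1.49-fold and the spindle gene Nusap1 1.43-fold lower. None passed the rule, 3 had a widened interval below 1, Bub1b and Nusap1 among them, and 0 above, while those of Cdc6 and Ccne1 included 1. Nusap1 overlaps Oip5 by 208 bases (146 and 96 counts), so its counts are uncertain. Mki67 (2189 and 1659 counts) and the replication clamp gene Pcna (1034 and 1226 counts), both picked after their values were seen, had ratios on either side of 1, with widened intervals that included 1. Replication-dependent histone genes, 10 of 20 measured, had a median 1.62-fold lower (log2 -0.69), also below all random lists, and 9 of 10 had a ratio below 1. Hist1h1b (140 and 48 counts) and Hist1h1d (37 and 17 counts) were lower by the rule. Hist1h2ab was 1.75-fold and Hist2h2ac 1.70-fold lower without passing it. Widened intervals lay below 1 for Hist1h1b and Hist1h2ab and included 1 for Hist1h1d and Hist2h2ac. The member with a ratio above 1 was Hist1h2bc (624 and 890 counts), named after its values were seen, whose widened interval of 1.01 to 2.02 lay above 1. Most histone transcripts lack a poly(A) tail and have close paralogs, so these counts cover only part of them. Whether that part follows proliferation was not tested.

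Contractile and TGF-beta response genes were also lower as a group. The median of 21 measured genes was 1.24-fold lower (log2 -0.31, percentile 0.01), with 14 ratios below 1. Edn1, endothelin 1, was lower by the rule from 34 and 10 counts, with a widened interval of 0.0239 to 1.75. The TGF-beta feedback inhibitor Smad7 had a log2 ratio of -0.86 and Tgfbi -0.63, and both widened intervals included 1. With genes under 200 summed counts left out, the list was at percentile 4.6 and no longer stood apart.

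Interferon-stimulated genes were lower as a group. The median of 33 genes was 1.17-fold lower (log2 -0.23, percentile 0.73), and 23 had a ratio below 1. Ifit3, an interferon-induced antiviral gene, was lower by the rule at 6.14 against 16.6 CPM (ratio 0.370, counting interval 0.285 to 0.475, widened 0.171 to 0.742). Ifit1 had a log2 ratio of -0.90 (widened interval of the ratio 0.270 to 1.02) and Ifit3b, a close paralog of Ifit3 with which reads could be shared, -0.88. The interferon regulator Irf7 had 0.81 from 38 and 67 counts, and the widened intervals of Ifit3b and Irf7 included 1. In the whole list, 3 members had a widened interval below 1, Ifit3 among them, and 0 above.

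Fatty acid oxidation genes were higher as a group and fatty acid and triglyceride synthesis genes lower, by small amounts. The median of 24 fatty acid oxidation genes was 1.13-fold higher (log2 0.17, percentile 99.4), with 17 ratios above 1. The nuclear receptor Ppara had a log2 ratio of 0.58, the carnitine transferase Cpt1b 0.53, the thioesterase Acot2 0.43 and the kinase Pdk4 0.36. Cpt1b (31 and 45 counts) overlaps a noncoding RNA gene (224 and 222 counts) over 9458 bases, so its counts are uncertain. The median of 22 fatty acid and triglyceride synthesis genes was 1.09-fold lower (log2 -0.13, percentile 1.35), with 16 ratios below 1. Thrsp had -0.43, the acyl-CoA synthetases Acss2 and Acsl1 -0.39 each, while the phosphatidate phosphatase Lpin1 had 0.66. No gene of either list passed the rule, and among those named the widened interval left out 1 for Lpin1 alone. Fatty acid oxidation was at percentile 95.8 with genes under 200 summed counts left out and at 85.7 with summed values. The synthesis list was at 2.94 with no filter, 4.84 against unmatched random lists and 3.93 with the trend on GC content and length removed.

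**Figure D3:**
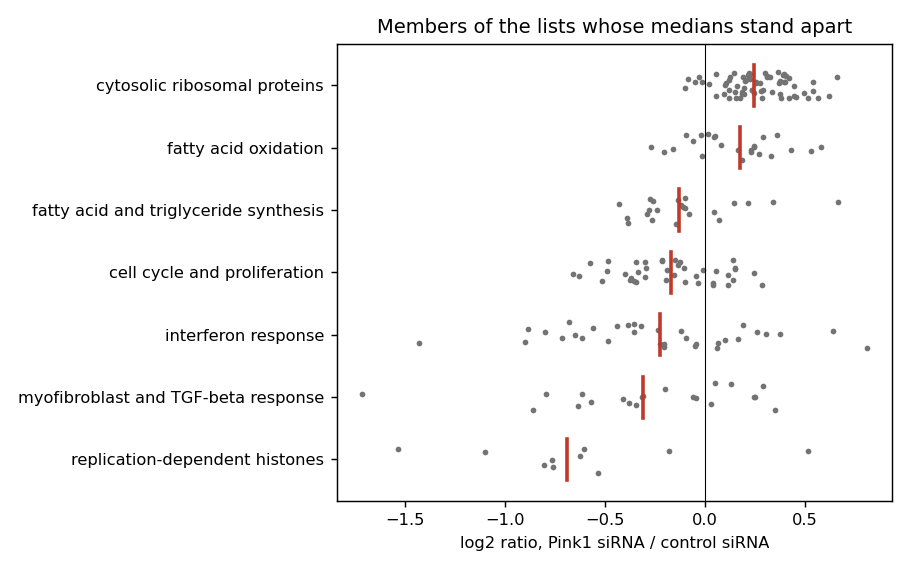
Each grey point is the log2 ratio (x axis, Pink1 siRNA over control siRNA) of 1 measured member of the 7 lists that stood apart, with vertical jitter only for legibility, and red bars are medians. The ribosomal protein points sit mostly above 0, at 62 of 67, the histone points mostly below 0, at 9 of 10, and each of the 7 lists has members on both sides of 0.

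Adipocyte identity genes were detected at similar levels in both libraries. The median of 22 measured mature adipocyte markers was 0.01 on the log2 scale (percentile 47.4), and none passed the rule. Adipoq, the hormone adiponectin, was at 308 against 310 CPM, the lipoprotein lipase gene Lpl at 815 against 817, and the fatty acid carrier Fabp4 at a ratio of 1.14. Cfd had a ratio of 1.12. Values further from 1 were seen for the resistin gene Retn (376 and 562 counts), the fatty acid transporter Cd36 (461 and 621), the lipid droplet coat gene Plin1 (275 and 167), Tusc5 (86 and 147) and the insulin-regulated glucose transporter Slc2a4 (49 and 25), and all 5 widened intervals included 1. Cdo1 (1083 and 1598 counts), named after its values were seen, was the 1 marker with a widened interval above 1, and 0 lay below. Lep had 0 counts in both libraries. The preadipocyte factor Dlk1 was among the most abundant transcripts, with 116628 and 130666 counts, so both libraries held preadipocyte and adipocyte transcripts. Its widened interval was 1.02 to 1.23, but its log2 ratio of 0.16 lay within the interquartile range of its twentieth of level (-0.08 to 0.21).

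The adipogenic regulators did not stand apart as a group either. The median of 22 adipogenic transcription factors was 0.01 (percentile 45.8), with Pparg at a ratio of 1.04, Cebpa at 0.891, Cebpb at 1.18 and Cebpd at 1.31. The widened interval lay above 1 for Klf5 (log2 0.92), and it included 1 for Pparg, Cebpa, Cebpb, Cebpd, Stat5b (0.56), Klf4 (0.46) and Zfp467 (-0.45). The 22 adipogenesis repressors had a median of 0.01 (percentile 41.3). Gata3, which restrains preadipocyte conversion, was higher by the rule from 64 and 132 counts, with Klf7 at 0.69, Wnt6 at 0.54 and Id2 at -0.52. In the lipolysis and lipid droplet list (17 genes, median 0.08, percentile 80.7), Fitm2 was higher by the rule from 20 and 42 counts, Bscl2 had 0.50 and Aqp7 -0.50. The 18 progenitor markers had a median of 0.00 (percentile 37.4). Pi16, a fibroblast progenitor marker, was higher by the rule from 20 and 69 counts, Cd24a had 0.83, F3 0.68 and Clec11a -0.63. Widened intervals included 1 for Gata3, Wnt6, Id2, Fitm2, Bscl2, Aqp7 and Clec11a and lay above 1 for Klf7, Pi16, Cd24a and F3. With a common widening factor, that of Pi16 included 1 (0.933 to 18.2).

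Mitochondrial gene groups other than fatty acid oxidation did not stand apart. All 76 nuclear-encoded oxidative phosphorylation subunits were measured, with a median of 0.07 (percentile 87.7), none past the rule. Sdhd had 0.66, Ndufa11 0.46, Ndufb2 0.39 and Ndufc1 0.38. The TCA cycle list had a median of 0.06 (percentile 73.0), with Suclg2 at -0.40, Pcx at -0.33 and Idh3a at 0.33. Biogenesis and dynamics genes had a median of -0.06 (percentile 22.7). Their coactivators Ppargc1a and Ppargc1b were at -0.53 and -0.61, with Mief2 at 0.77 and Sirt3 at 0.52. Mitochondrial chaperones and proteases had a median of -0.03 (percentile 20.8), with Trap1 at -0.38, Afg3l2 at -0.35, Hspd1 at -0.20 and Phb2 at -0.19. Of the mitochondrial genes named here, Sdhd had a widened interval that left out 1. Of the 26 symbols listed for genes encoded by mitochondrial DNA, 0 were among the deposited symbols, so this list could not be described. Ucp1, the uncoupling protein of thermogenic fat, had 0 and 4 counts, and only 3 thermogenic genes were measured.

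Genes for secreted factors that act on bone did not stand apart (17 measured, median -0.08, percentile 9.24), and none passed the rule. The osteoclast cytokine gene Tnfsf11 and its decoy receptor Tnfrsf11b had 0 counts in both libraries, and Il6 had 0 and 2. Csf1, the macrophage growth factor, was at a ratio of 0.893 and the chemokine Ccl2 at 0.876. Rarres2, the adipokine chemerin, had a log2 ratio of -0.80 from 614 and 352 counts, but it overlaps Lrrc61 (650 and 448 counts). The lipocalin Lcn2 had 0.73, Wnt5a -0.57 and Nampt 0.53, and Nampt overlaps Gdap10 (240 and 238 counts). Of 26 osteoblast markers 11 were measured, with a median of -0.11 (percentile 8.17) that took the other sign at a summed count of 200 (0.02) and with summed values (0.04). Runx2, the osteoblast master regulator, had 217 against 419 counts (ratio 0.519, counting interval 0.438 to 0.612, widened 0.315 to 0.835). This ratio is just short of the rule, and Runx2 overlaps Supt3 (196 against 191 counts), so its counts are uncertain. Phex had a log2 ratio of 0.57 and the osteopontin gene Spp1 -0.36. Among 6 measured osteoclast markers (median -0.15, percentile 17.0), the gelatinase Mmp9 had 570 against 1074 counts (log2 -0.91, widened interval of the ratio 0.358 to 0.778), Nfatc1 had -0.56, Itgb3 -0.22 and Clcn7 -0.08. The 42 matrix genes had a median of 0.04 (percentile 33.5). Timp3 was lower by the rule from 61 and 25 counts, Col1a1 had a ratio of 1.15, Thbs1 a log2 ratio of -0.68, Loxl2 0.89 and Col15a1 0.68. Of the measured genes of these lists named here, widened intervals lay below 1 for Rarres2, Runx2, Mmp9 and Thbs1. They lay above 1 for Nampt and Col1a1 and included 1 for the rest, Timp3 among them. The log2 ratio of Col1a1, 0.20, still lay within the interquartile range of its twentieth of level (-0.08 to 0.21).

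Apart from the interferon response list, no stress or inflammatory list stood apart, and each of the lists below held from 0 to 3 genes past the rule. In the NRF2 and antioxidant list (31 genes, median 0.01, percentile 33.2), the quinone reductase Nqo1 was lower from 229 and 112 counts and the cystine transporter Slc7a11 from 61 and 14, while Hmox1 had 0.57 and G6pdx 0.45. In the integrated stress response list (median 0.00, percentile 43.3), Slc7a11 and Sesn2 (55 and 27 counts) were lower by the rule and Gdf15 higher (25 and 52), with Aldh18a1 at 0.51. The endoplasmic reticulum stress list had a median of -0.05 (percentile 9.20), with Pdia4 at -0.64, Dnajb9 at -0.54, Hyou1 at 0.19 and Edem1 at -0.17. Cytokine and NF-kB target genes had a median of -0.07 (percentile 16.9). Cxcl10 was lower by the rule (45 and 17 counts), and Il33 and Tnfaip3 had 0.62 and 0.59. Among immediate early genes (median -0.08, percentile 12.8), Fos was lower by the rule from 148 and 42 counts (ratio 0.286, counting interval 0.196 to 0.402), with Egr3 at -0.81, Fosl1 at -0.64 and Egr1 at -0.55. The senescence and p53 list had a median of 0.07 (percentile 74.0), with the cell cycle inhibitor gene Cdkn1a at a ratio of 0.780 and Igfbp3 at a log2 ratio of 0.78. Widened intervals left out 1 for Nqo1, Slc7a11, Pdia4, Fos and Egr1, and included it for the other genes named here. With a common widening factor, that of Slc7a11 included 1 (0.0283 to 1.03).

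Metabolic lists other than the fatty acid lists, and the reference list, also lay within the random range. Glycolysis genes had a median of 0.02 (percentile 51.0), with Slc16a3 at -0.80, Pfkfb3 at -0.70, Slc16a1 at -0.50 and Hk1 at -0.36. Hypoxia genes had 0.06 (percentile 75.2), with Adm at 0.81, Anln at -0.57, Mxi1 at 0.53 and Ankrd37 at 0.46. Cholesterol synthesis genes had -0.04 (percentile 33.9). Tm7sf2 was lower by the rule (38 and 11 counts), Stard4 had -0.89, Srebf2 0.43 and Mvk 0.40. Insulin and growth factor genes had -0.04 (percentile 16.8), with Irs2 at -0.73, Igf2 at 0.65 and Foxo1 at 0.26. The 27 housekeeping genes had 0.03 (percentile 44.2), with Chmp2a at 0.49, Rpl13a at 0.34, Reep5 at 0.30 and Snrpd3 at -0.29. Widened intervals lay above 1 for Adm and Igf2 and included 1 for the other genes named here, Tm7sf2 and the 4 housekeeping genes among them.

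Markers of other cell types were few. Of the macrophage and leukocyte, endothelial, chondrocyte, and dopaminergic and neuronal lists, 3, 1, 3 and 3 genes were measured, too few for a percentile. Among them Syn1, a synaptic vesicle gene named after its values were seen, was higher by the rule (63 and 129 counts), with a widened interval that included 1. Of 17 muscle markers 5 were measured, with a median of -0.71 (percentile 6.95). Ttn (92 and 32 counts) and Tnni1 (44 and 19) were lower by the rule, Tnnt3 had -0.71 and Des 0.42, and the widened intervals of all 4 included 1.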

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

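The intervals widened for excess spread and the removal of the GC and length trend were chosen after the data were seen. No paired analysis was possible because each group has 1 library. For the same reason no library could be left out, and other splits of the samples were not possible. Under total-count, median-of-ratios or upper-quartile scaling, or with 5 added, no log2 ratio of the 176 genes named by the fixed rule changed sign. These genes include Pink1. Other scalings moved the median log2 ratio of measured genes by less than 0.1, from 0.00 to -0.04 with total counts, and changed no list's standing. List medians took the other sign for 10 lists with total counts and 5 with upper-quartile scaling, 5 with the GC and length trend removed, 1 with no filter, 5 with summed values and 1 at a summed count of 200. These medians were at most 0.11 in size, none was of a list that stood apart, and no direction is read from them. The number of genes past the rule of size depended on the thresholds: 597 higher and 853 lower with no filter, 26 and 40 at a summed count of 200, 633 and 774 at a ratio of 1.5, 23 and 44 at a ratio of 4, 47 and 80 with the interval widened by a common factor, and 48 and 81 with that widened by the spread at each level. Fewer or more genes are admitted by construction in each case. Fatty acid and triglyceride synthesis no longer stood apart with no filter (percentile 2.94), against unmatched random lists (4.84) or with the GC and length trend removed (3.93). Fatty acid oxidation no longer did at a summed count of 200 (95.8) or with summed values (85.7), and the myofibroblast and TGF-beta list at a summed count of 200 (4.6). The cause was not tested. Lists that newly stood apart were muscle markers against unmatched random lists (0.06) and immediate early genes (1.05) and osteoclast markers (0.16) with summed values. The ribosomal protein, cell cycle, histone and interferon lists stood apart under every alternative run. In simulated data with counting error alone, 67 of 67 genes altered by 2.5-fold and 0 of 67 altered by 1.5-fold passed the rule. That setting leaves out the excess spread, which adds to counting error among genes of few counts. With the spread of the 2915 genes of lowest level, 54 of 67 passed at 2.5-fold, and 489 unaltered genes passed too. Whether depth limited the calls therefore cannot be told.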

Other observations

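The tests of excess spread and of the number of libraries, and the choice to rest the Mdm2 test on measured neighbours without Mdm2 itself, were made after the results were seen. Mdm2, the ubiquitin ligase that restrains p53, ranked 6 by count in both libraries, with 81638 and 82471 counts (5828 and 5888 CPM). Its neighbour Slc35e3 on chromosome 10, which starts at 117733678 against 117688875 for Mdm2 (mm10), had 21140 and 27384 counts, rank 38 and 31. Also within 1 Mb, Cct2 (7632 and 7576 counts), Yeats4 (5499 and 5319), Nup107 (4612 and 4555), Rap1b (3659 and 4043) and Cpsf6 (2405 and 2039) were abundant, while the other 6 measured neighbours had fewer counts, among them Frs2 (488 and 393), Cpm (274 and 186), Rab3ip (257 and 188) and Mdm1 (186 and 216). A hypothesis is that this line may carry extra copies of the region. The median of the 12 measured neighbours, without Mdm2, was 70.6 CPM against 27.5 CPM for all measured genes, at percentile 97.1 of 10852 windows of as many neighbouring genes. That falls between the bounds set beforehand for and against, so the test leaves it open, and DNA was not measured here.

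The differences between the libraries exceed counting error at every level of expression. In the lowest twentieth of measured genes (median 53 summed counts), squared differences were 5.66 times the counting variance. Among all rows, measured or not, 279 had 0 counts in the control and at least 5 in the Pink1 siRNA library, and 405 the reverse. If reads were independent, 11.8 would be expected in each direction. PCR copies of the same molecules and differences between the cultures both give such a spread, and with 1 library per group they cannot be told apart. The factor in the highest twentieth was 22.6 times that in the lowest, which argues against copies at one fixed rate as the whole cause and leaves open gene-specific differences that grow with the level. Whether those come from the siRNA, the culture or the preparation was not tested.

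Cell cycle genes were lower in the Pink1 siRNA library. Removing the trend on GC content and transcript length left the list at percentile 0 (median log2 ratio -0.17 before and -0.14 after), which argues against that bias as the whole cause. Fewer dividing cells in that culture is a candidate explanation. A set of 46 other cell cycle genes, chosen without sight of their values, had a median of -0.11 (percentile 2.10), with 32 ratios below 1. That set comes from the same 2 libraries, so it cannot tell fewer dividing cells from another cause of lower cell cycle transcripts. Replication genes of the fixed list, picked after their values were seen, were mixed. Mcm4 (0.11), Mcm5 (0.14), Mcm6 (0.28) and Pcna (0.25) had log2 ratios above 0. Mcm2 (-0.19), Mcm3 (-0.04), Mcm7 (-0.30) and Rrm2 (-0.30) lay below. With 1 library per group, an effect of the siRNA cannot be told apart from a difference in density, timing or preparation between the cultures.

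Ribosomal protein genes were higher in the Pink1 siRNA library. The list stayed at percentile 100 with the GC and length trend removed (median 0.24 before and 0.23 after), which argues against that bias as the whole cause. A shift of the wider class of translation-machinery transcripts may be involved: 23 translation factor and snoRNA host genes outside the list had a median of 0.17 at percentile 98.7 (20 ratios above 1), in a test set before their values were looked at. These genes come from the same 2 libraries, so they show that the pattern extends beyond the list and not what caused it. With 1 library per group, the siRNA again cannot be told apart from the culture or the preparation. The Pink1 siRNA library also had 14432 rows with a count against 14682 in the control, despite its larger total.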
